A study of Arabidopsis thaliana with 4 samples.

How the data were processed

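The series comprised 4 one-colour slides from leaves of Arabidopsis thaliana Col-0: 2 for a mock-inoculated sample and 2 for a sample inoculated with Pseudomonas syringae ES4326, both taken 24 h after injection. Per the labels' protocols, total RNA was amplified in vitro as amino allyl RNA and coupled to the dye Alexa555. The series' design text describes the slides as 2 of one sample in each group, so they were treated as technical replicates of 1 RNA sample per group, and p-values measure only the spread between slides.

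The authors deposited one table of 576 probes with one value on a log scale per slide, read here as log2. The scanner, the background correction, the scaling between slides and the base of the logarithm are not given in the sources used here. The values had no missing cell. The highest, 12.3, lies above the natural logarithm of a 16-bit scanner's maximum (11.09), and the values of mock slide 1 spanned 10.5 units, which is 1433-fold if the base is 2 and 35781-fold if it is e. The base of 2 was therefore taken as the more likely reading, and the natural logarithm was run as an alternative. The values were used with the scaling the authors gave them. No depth or number of spots per probe was given.

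Probes were named from the platform annotation, which pairs 181 probes with 1 gene symbol each and none with several; 395 probes stayed unnamed here and may include control spots. Of the 181, 180 were matched by Entrez gene ID to locus tags and current symbols of the TAIR10.1 gene table, and 1 kept its annotated name. That table's coordinates were not used, because no genome build is named for the array. No gene had more than 1 named probe.

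The difference between groups was fitted on the log2 values of the 181 named genes with limma 3.58.1 in R 4.3.3 (lmFit with group as the sole term, eBayes without trend), with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and an absolute difference of at least 1 log2 unit (2-fold). eBayes estimated 1 shared variance for the named genes, so every difference had the same SE, 0.209 log2 units, and a confidence interval of ± 0.411. The slide error did vary with level: the SD per mock slide was 0.313 in genes above the median level and 0.184 below it. The shared SE may therefore be too small for genes whose slides lay far apart, such as ATHM2 (mock SD 0.85). The very small p-values follow from the shared variance. When the error was estimated over all 576 probes, the same 70 named genes were called, with adjusted p of at most 0.00319. Slide agreement was summarised by the SD of the difference between slides divided by the square root of 2, and by correlations across genes. Gene lists (17 lists, 254 genes) were matched by locus, and a list with at least 3 named members was placed among 10000 random lists of the same size, matched on mean level in 5 bins.

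Genes were named by a rule fixed before the data were examined: the 12 largest rises and up to 12 largest falls among called genes whose Psm slides both lay beyond both mock slides (11 falls qualified), up to 4 members of each list with at least 3 named members, the housekeeping genes, and PR1, PAD3, ICS1 and PDF1.2 where named, of which only PDF1.2 was. The members of smaller lists are also given.

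Simulated data used the real mock levels and 1 slide error SD per group for all genes (181 genes, 60 changed, 20 draws). Rises and falls were equally many, and no offset was set between groups. The fit recovered 99.3% of changes of 1.5 log2 units and 100% of changes of 3. All had the right sign, and 0% of unchanged genes were called. The simulation shares the fit's assumption of equal variances, so it checks the procedure and does not support the calls in the real data. The alternatives comprised the slide number as a block, each slide left out, median centring, quantile normalization, omission of the dimmest 25% of genes, a variance trend, other fold limits, unmoderated variances, all 576 probes and natural logarithms. The following alternatives, fixed in advance, were not run: scaling to the housekeeping list, of which 1 member was named, and testing several probes of a gene separately, since no gene had several. Slide numbers are shared by both groups, but the deviations of slides with the same number correlated by 0.04 across the named genes and by 0.163 across all 576 probes. No label says that a number marks a shared batch or day, so the slides were taken to share only a number. Figures were drawn with matplotlib 3.10.9.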

Results

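Messenger RNA levels were measured in leaves of Arabidopsis thaliana, accession Col-0, on a small array made for plant-pathogen work. Leaves of plants aged 33 days were injected either with Pseudomonas syringae pv. maculicola ES4326 (Psm), a virulent bacterial pathogen of Arabidopsis, suspended in 5 mM MgSO4, or with 5 mM MgSO4 alone as the mock control, and were harvested 24 h later. The series set out to evaluate how the small array performs against the whole-genome ATH1 array. Values from the ATH1 array were not analysed here. Each group had 1 RNA sample, hybridised to 2 slides, so the 4 slides gave the spread between slides of one sample and a comparison of 2 RNA samples. They gave no measure of the spread between plants or between inoculations. The table held 576 probes, of which 181 could be given a gene name, and the results below concern those 181 genes unless stated otherwise. Levels are given in log2 units. The base of the logarithm is not given in the sources used here and was taken to be 2, so every fold below rests on that reading. Over all 576 probes the median level was 3.44 and 3.43 on the mock slides and 4.29 and 4.37 on the Psm slides. The precision of each value is limited by the number of slides, 2 per group.

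The first comparison asked how closely slides of the same RNA sample agreed. Between the Psm slides the SD per slide, taken over genes, was 0.144 log2 units, and levels correlated across genes with Pearson's r = 0.995 and Spearman's rho = 0.995. Between the mock slides the SD per slide was 0.257 log2 units, with r = 0.979 and rho = 0.971. Genes are not independent replicates, so no p-value was attached to these correlations. The median absolute difference between slides was 0.112 log2 units for Psm and 0.225 for mock. No gene was 2-fold or more apart between the Psm slides, and 3 of 181 (1.66%) were between the mock slides. The widest gap among the mock slides was that of AT3G51730, at 5.90 on slide 1 and 4.27 on slide 2. Next came ATHM2, thioredoxin m2 of the chloroplast, at 6.08 and 4.87, and AT5G65360, a histone H3.1 gene, at 7.36 and 8.44. BIP1, an HSP70 chaperone of the endoplasmic reticulum, stood at 5.90 and 4.95 on the mock slides. AT5G60390, which encodes translation elongation factor EF1A, stood at 8.81 and 7.89. The median over genes of slide 1 minus slide 2 was -0.11 log2 units for mock and 0.013 for Psm.

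**Figure D1:**
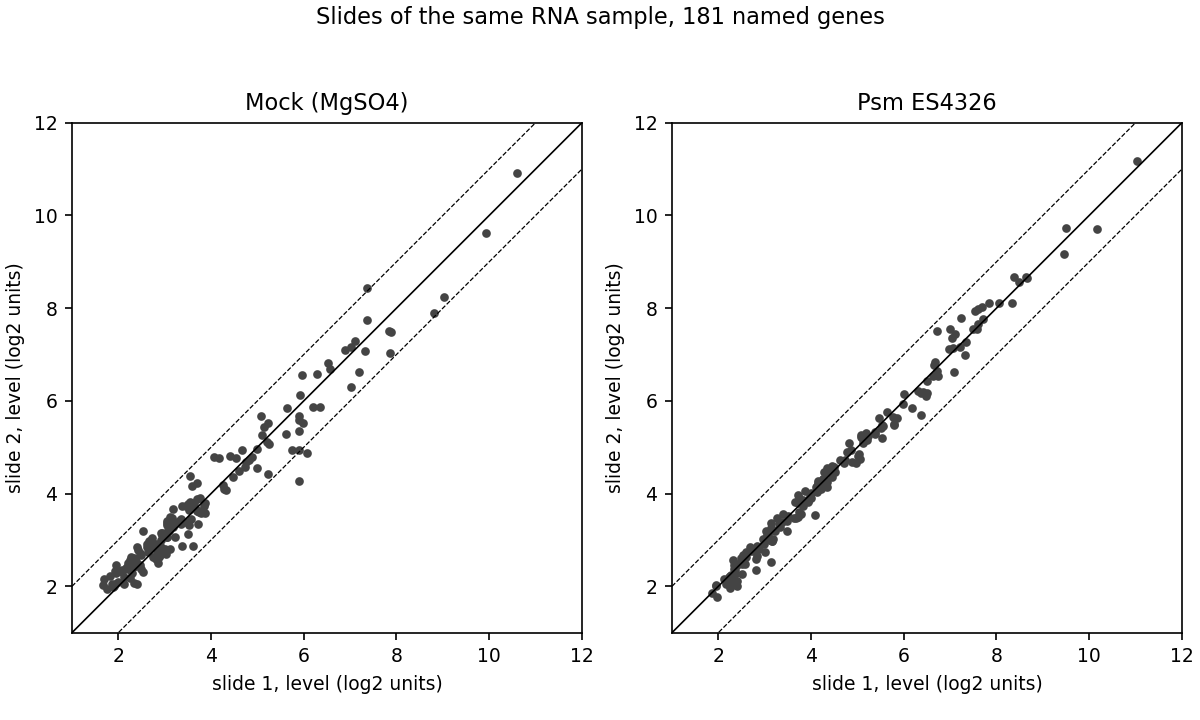
Level of each of the 181 named genes on slide 1 (x axis) and slide 2 (y axis), in log2 units, for the mock sample (left) and the Psm sample (right). The solid line marks equal levels and the dashed lines a 2-fold difference: 3 genes reach or pass the dashed lines in the mock panel and 0 in the Psm panel.

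The second comparison asked which genes differed between Psm-inoculated and mock-inoculated leaves. A total of 59 genes rose and 11 fell, while 111 were not called, at an adjusted p under 0.05 (limma, Benjamini-Hochberg adjustment over the 181 genes) with at least a 2-fold difference. With the deposited scaling, 35 rises and 5 falls were of 4-fold or more, and 9 rises and 1 fall of 16-fold or more. For all 70 called genes both Psm slides lay beyond both mock slides. The same held for genes that were not called, such as WRKY29 and AT4G26410 (0.038 log2 units), so it adds little to the calls. The adjusted p of the called genes was 5.33e-06 at most. The test took its error from slides of one RNA sample per group. It shows that the 2 groups of slides differed beyond the spread between slides of one sample. A technical error shared by both slides of a group is not in that spread, and the conditions are not tested across plants. Slide medians were higher by 0.896 log2 units in the Psm sample, and the scaling that was applied between slides is not given in the sources used here. When each slide was centred on its own median, 35 genes rose and 40 fell, so that rises made up 46.7% of calls against 84.3% with the deposited scaling. Of these, 19 rises and 10 falls were of 4-fold or more, and the widest difference was then a fall, of AT3G16370 (-5.37). By construction such centring draws rises and falls toward an even balance, so it does not show which balance is the true one. It moved the median difference over genes from 0.388 to -0.508 log2 units, past zero. After this centring, 35 of the 59 rises and 11 of the 11 falls were called again in the same direction.

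**Figure D2:**
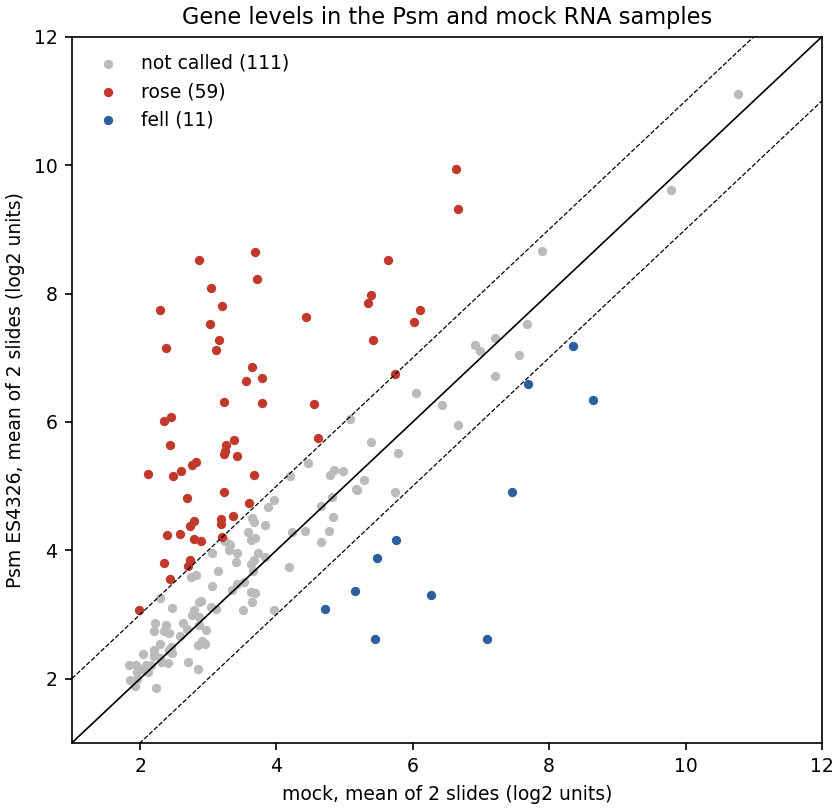
Mean level of each of the 181 named genes in the mock sample (x axis) and the Psm sample (y axis), in log2 units, each the mean of 2 slides. Red points mark the 59 genes that rose, blue points the 11 that fell and grey points the 111 not called. Dashed lines mark a 2-fold difference from the solid line of equal levels.

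UGT76B1 (AT3G11340), a glucosyltransferase that conjugates salicylic acid and isoleucic acid, rose from 2.87 ± 0.46 in mock to 8.52 ± 0.06 in Psm (mean ± SD, n = 2 slides each), a difference of 5.65 ± 0.21 log2 units (SE) or 50.2-fold. AT1G68620, an alpha/beta-hydrolase gene, rose by 5.45 log2 units (43.7-fold). The 2 differed by less than the SE, and AT1G68620 had the larger rise without mock slide 1 (5.37 against 5.32) and with quantile normalization (4.96 against 4.82). AT2G34810, of the berberine bridge enzyme family, rose by 5.05 (33.0-fold), and AT2G32150, which encodes a haloacid dehalogenase-like hydrolase, by 4.97 (31.3-fold). AT1G09500, a member of the family of cinnamyl alcohol dehydrogenase-like reductases, rose by 4.78 log2 units. AT3G59930, a defensin-like gene, went from 3.204 ± 0.23 to 7.80 ± 0.26 (mean ± SD, n = 2 slides each), which is 24.2-fold. CHI (AT2G43570), annotated as a putative chitinase, an enzyme class that acts on fungal cell walls, rose by 4.51 log2 units or 22.8-fold. AT4G39670, of the glycolipid transfer protein family, rose by 4.50, AT1G05340 by 4.13. AT2G28400 rose 15.98-fold. AT3G13950 rose by 3.66 log2 units, and UGT76E12 (AT3G46660), another glucosyltransferase, by 3.62 (12.3-fold). Each of these 12 differences carried the same SE of 0.21, because limma estimated a single error variance for all genes. Of the 12, 4 had a mock level under the lower quartile of both mock slides, AT1G68620 among them, and near the lowest signals a fold depends on how background was removed. All 12 were called again with median centring, with quantile normalization and with each slide left out, but their folds depend on the scaling. Median centring divides each of them by 1.86, to 27.0-fold for UGT76B1 and 6.60-fold for UGT76E12. Quantile normalization gave 28.2-fold for UGT76B1, 9.74-fold for CHI and 7.29-fold for AT2G28400.

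The falls were led by AT3G16370, which encodes a lipase of the GDSL family and went from 7.09 ± 0.10 to 2.62 ± 0.03 (mean ± SD, n = 2 slides each), a decrease of 22.2-fold. TUB6, a beta-tubulin gene, fell by 2.96 log2 units (7.77-fold), and AT3G18050 fell by 2.83 (7.12-fold). AT2G37190, which encodes a cytosolic ribosomal protein, fell by 2.54 log2 units, and SIR, the sulfite reductase of sulfate assimilation, fell by 2.30. LHCB4.3, a light-harvesting protein of photosystem II, fell by 1.79 log2 units, and AT3G12390, a subunit of the nascent polypeptide-associated complex, fell by 1.63. AT2G04700, the catalytic subunit of ferredoxin-thioredoxin reductase, and ATHM2 each fell by 1.60. AT5G60390, the EF1A gene and the only housekeeping gene among the named probes that had been listed in advance, fell by 1.16, and AT4G40030, a histone H3.3 gene, fell by 1.103. Median centring multiplies the fold of each fall by 1.86, so that AT3G16370 stood at -5.37, TUB6 at -3.85, AT3G18050 at -3.73, SIR at -3.19 and AT4G40030 at -1.999 log2 units. With quantile normalization they stood at -4.99, -3.73, -3.56, -3.34 and -2.24. The probes of AT5G60390 and AT4G40030 have near-identical gene copies elsewhere in the genome, so their signal is not certain to come from one locus. ATHM2, AT5G60390 and AT4G40030 no longer met the 2-fold limit without mock slide 1, where their differences were -0.995, -0.707 and -0.902 log2 units. When each gene's own variance was used in limma without sharing across genes, 5 of the 11 falls and 50 of the 59 rises were called. The falls not called then were AT2G37190, SIR, AT2G04700, ATHM2, AT5G60390 and AT4G40030.

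**Figure D3:**
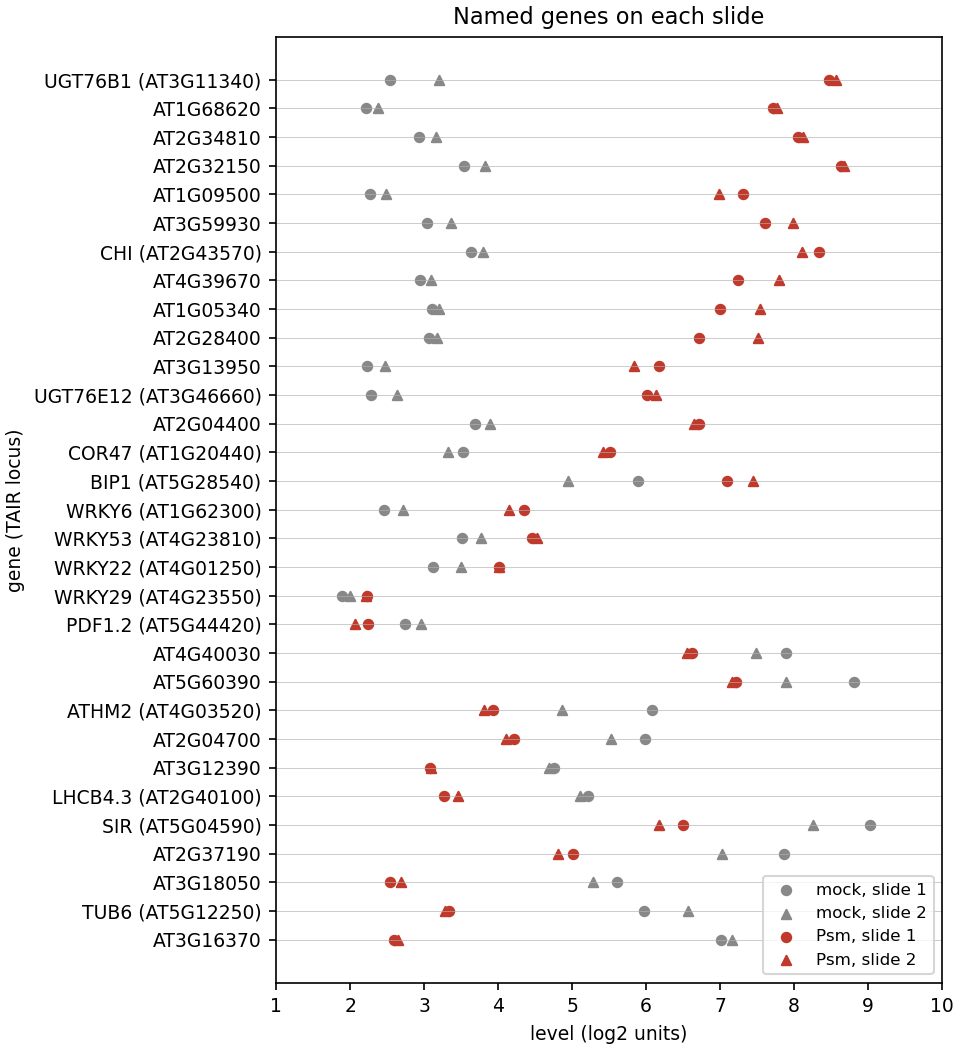
Level in log2 units (x axis) of each gene named by the fixed rule (y axis), on the 2 mock slides (grey) and the 2 Psm slides (red), with circles for slide 1 and triangles for slide 2. UGT76B1 at the top lies at 2.54 and 3.199 on the mock slides and at 8.48 and 8.56 on the Psm slides, and AT3G16370 at the bottom lies at 7.02 and 7.16 on mock and at 2.59 and 2.64 on Psm.

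Of 17 gene lists fixed in advance, WRKY transcription factors were the only one with 3 or more named members on the array. Of its 4 members WRKY6 rose, by 1.66 ± 0.21 log2 units (SE) or 3.16-fold, and 3 were not called. That call was lost with median centring (0.765) and quantile normalization (0.944). WRKY53, a regulator of leaf senescence and defence, differed by 0.86 log2 units (95% confidence interval 0.45 to 1.27) and WRKY22 by 0.70 (0.29 to 1.11). Both had an adjusted p under the threshold (limma, 0.000119 and 0.00178) but stayed under the 2-fold limit. The base of the logarithm decides this: read as natural logarithms, the values put WRKY53 at 1.24 and WRKY22 at 1.01 log2 units, both past the limit. WRKY29 differed by 0.27 log2 units (-0.14 to 0.68), with an adjusted p of 0.265 in limma. At the adjusted p alone 3 of the 4 passed, both over all genes and adjusted over the list alone, but this tally rests on the error model and the scaling. Over all genes WRKY22 did not pass without Psm slide 1 or without Psm slide 2 (adjusted p = 0.0557 in both). On each gene's own variance neither WRKY53 (0.0579) nor WRKY22 (0.115) passed, nor did they after median centring (0.838 and 0.315) or quantile normalization (0.507 and 0.206). The median of the list, 0.778 log2 units, lay at the 74.3th percentile of 10000 random lists of the same size matched on mean level, so the list did not stand apart from other genes of this array. Median centring lowers every gene by the same 0.896 log2 units, so the place of the list stayed at the 74.3th percentile. Its median became -0.12, and WRKY53, WRKY22 and WRKY29 changed sign because each had differed by less than that amount. WRKY29 then passed the adjusted p as lower (-0.624 log2 units, limma, adjusted p = 0.00239) but stayed under the 2-fold limit.

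For 5 other lists a single member was among the named probes. AT2G04400, indole-3-glycerol phosphate synthase of tryptophan synthesis, rose by 2.89 ± 0.21 log2 units (SE) or 7.42-fold, and by 1.995 with median centring and 1.608 with quantile normalization. COR47, a dehydrin that accumulates under cold and water stress, rose by 2.04 log2 units (4.12-fold), and by 1.146 with median centring and 1.003 with quantile normalization, just past the limit. BIP1 rose by 1.85 log2 units (3.61-fold), although it was 0.597 with quantile normalization and 0.958 with median centring, both under the limit. It was also not called on its own variance (limma, adjusted p = 0.119). PDF1.2, a plant defensin used as a marker of jasmonate and ethylene signalling, stood at 2.85 ± 0.16 in mock and 2.15 ± 0.13 in Psm (mean ± SD, n = 2 slides each). Its difference of -0.70 log2 units (95% confidence interval -1.11 to -0.28) was under the 2-fold limit, and it passed that limit with median centring, at -1.59, with quantile normalization, at -1.09, and with the values read as natural logarithms, at -1.003. AT5G60390 of the housekeeping list is described above. For the remaining 11 lists, which include salicylic acid signalling, pathogenesis-related proteins, photosynthesis and the markers of epidermal and vascular cells, no member was among the named probes, and they were not analysed here.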

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

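The tests in this part were chosen after the results were seen. Their exact and bootstrap intervals treat genes as independent, which they are not, so they may be too narrow. Many probes without a gene name, left out of the comparison above, also differed from the mock sample. With the same limits in a limma fit over all 576 probes, 171 of the 395 rose, 38 fell and 186 were not called. The share called was 52.9%, against 38.7% of the named genes in the same fit. These figures rest on the deposited scaling. Of the unnamed probes, 93 rose and 86 fell when each slide was centred on its median over all probes. With quantile normalization 86 rose and 79 fell. With the deposited scaling 21 of them rose and 7 fell by 16-fold or more, against 9 and 14 after centring. Probes 45 and 146 rose by 6.68 and 6.61 log2 units, and probes 105 and 229 fell by 7.23 and 5.23, in each case by more than any named gene, which held under both other scalings. Probe 105 stood at 11.8 and 10.4 on the mock slides and at 3.90 and 3.89 on the Psm slides.

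More genes rose (59) than fell (11). Little room to fall for dim probes stays open: among the genes brightest in mock 9 rose and 11 fell (45% rises, exact 95% interval 23.1% to 68.5%), while among those brightest over both samples 23 rose and 4 fell (85.2% rises, 66.3% to 95.8%). Both splits are tied to the outcome, since a fall starts from a high mock level and a rise lifts the mean. A uniform offset between the Psm and mock slides stays open too. The most frequent difference among genes above the median level was -0.12 log2 units, but its 95% bootstrap interval (-0.33 to 2.50) contains 0.448, the midpoint between no offset and the 0.896 by which the slide medians differ. A response to the bacterium is the biological alternative, and it was not tested because each group holds 1 RNA sample.

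The mock slides differed 1.78 times as much as the Psm slides. Noise of dim probes is argued against as the whole cause. The SD per mock slide was larger in genes above the median level (0.313, 95% bootstrap interval 0.249 to 0.372) than in those below it (0.184). That level was the mean over all 4 slides, so genes dim in mock that rose, such as UGT76B1, counted as above it. The widest mock gaps, of AT3G51730, ATHM2 and AT5G65360, were in genes above the named-gene median of both mock slides (3.32 and 3.36). A level-dependent curve between the mock slides is argued against as the whole cause, since after a loess curve was removed the SD was 0.242 for mock and 0.138 for Psm. With RNA of the Psm sample in a mock slide, at least 90% of genes over 1.5-fold apart would lie nearer Psm on the same slide. Of these genes, 10 of 17 were nearer on slide 2 (58.8%, exact 95% interval 32.9% to 81.6%). They were chosen by their mock gap, not by their difference from Psm, so the tally cannot settle this. The 12 largest rises all stood nearer to Psm on mock slide 2, as did every called fall except AT3G16370 and TUB6. For the rises this means a higher level on slide 2, which most genes had (median of slide 1 minus slide 2, -0.11 log2 units). Their direction therefore does not show Psm RNA. Other rises, such as BIP1 (5.90 and 4.95) and GSTF3 (7.02 and 6.31), were nearer on slide 1. Psm RNA enough to move ATHM2 from 6.08 to 4.87 on slide 2, with Psm at 3.87, would also lift the large rises strongly. Yet the 12 largest rises stood at 3.82 or lower on mock slide 2, and at 5.84 or higher on both Psm slides. On mock slide 1, where AT3G51730 stood at 5.90 against 6.04 in Psm, they stood at 3.63 or lower. These levels argue against Psm RNA as the cause of the widest mock gaps. A small share of it in a mock slide stays open. A difference in labelling, hybridisation or printing of one slide stays open, and no biological explanation was tested, since both slides are described as one sample.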

How the results depend on the processing

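The balance of rises and falls moved with the scaling between slides, and which scaling is right stays open. Median centring of the named genes gave 35 rises and 40 falls, as did centring on all 576 probes, an alternative added after seeing the data; quantile normalization gave 36 and 36. The total count stayed within 1.5 times (75, 75 and 72 against 70). By construction, these scalings draw the balance toward even, and centring lowers every Psm-minus-mock difference by 0.896; the median difference over genes went from 0.388 past zero to -0.508 with centring and -0.183 with quantile normalization. The percentile of the WRKY list stayed at 74.3 with centring and was 67.6 with quantile normalization. The median of the WRKY list was -0.118, -0.117 and 0.00984 under these 3 settings; WRKY53 stood at -0.0398, -0.0386 and -0.154, WRKY22 at -0.196, -0.195 and -0.251, and WRKY29 at -0.624, -0.623 and 0.174. WRKY6 and BIP1 were not called under any of the 3, and PDF1.2 was called as lower under all of them. With no fold limit 104 genes passed, 85 higher and 19 lower, and with a 1.5-fold limit 93, 78 higher and 15 lower. Unmoderated variances, added after seeing the data, gave 50 rises and 5 falls; fewer degrees of freedom per gene are part of that setting. Natural logarithms, also added, gave 76 and 15, and WRKY53 (1.235), WRKY22 (1.01) and PDF1.2 (-1.003) then passed the 2-fold limit. Leaving out each slide in turn gave 68 to 74 calls, 57 to 63 rises, 9 to 11 falls and a WRKY median of 0.621 to 0.935; the lone slide left in a group was assumed to vary like the other group's. The percentile of the WRKY list ranged from 59.1 without the dimmest 25% of genes to 93.7 without mock slide 2. With the slide number as a replicate block, 70 genes were called, 59 higher and 11 lower, all of them the same genes as without it; slides with the same number deviated together with r = 0.04 over named genes and 0.163 over all probes, and no label pairs them. The variance trend and the error model over all 576 probes also gave those 70 genes. The SD per slide moved by less than 1.5 times under every setting run. Levels near the lowest values of a slide (1.499 to 1.83 over all probes) limit how far a fall, or a rise from a dim mock level, can be measured; 12 of the 59 rises started under the lower quartile of both mock slides.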

Other observations

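Genes in this part were picked after their values were seen, and no hypothesis was tested on them; values in brackets are those after median centring. Of 6 genes matched as glucosyltransferases by symbol or synonym, 3 rose and 3 were not called. Family members without such a name were not counted. Beside UGT76B1 and UGT76E12, UGT85A2 rose by 1.14 log2 units (0.243, a lost call), while UGT84A3 differed by 0.63 (-0.26), IAGLU by 0.51 (-0.38) and UGT74B1, an enzyme of glucosinolate synthesis, by -0.31 (-1.21, called as lower). Among Hsp70 genes, AT3G09440 rose by 2.502 log2 units (1.61), Hsp70-2 by 2.34 (1.45) and BIP1 by 1.85 (0.958, a lost call). The small heat shock protein gene AT2G29500 differed by 0.95 (0.058) and the peptidyl-prolyl isomerase gene AT5G48570 by 0.79 (-0.107), and neither was called; read as natural logarithms, the values put both past the 2-fold limit (1.38 and 1.14). GRX480, a glutaredoxin that interacts with TGA transcription factors, rose by 3.07 log2 units (2.17). GSTF3, a glutathione transferase with a near-identical paralogue, rose by 2.65 (1.75). SDH1-1, the flavoprotein subunit of mitochondrial succinate dehydrogenase, rose by 2.598 (1.702). ATG8E, an autophagy protein, rose by 1.73 (0.83) and STZ, a zinc finger factor of abiotic stress responses, by 1.08 (0.183); both calls were lost with centring and with quantile normalization.

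Of 3 histone H3 genes, AT4G40030, an H3.3 gene, fell by 1.103 log2 units (-1.999), a call lost without mock slide 1. The H3.1 genes AT1G09200 and AT5G65360 differed by 0.90 and 0.77 and were not called; after median centring they stood at 0.008 and -0.13, and read as natural logarithms at 1.305 and 1.105, past the limit.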
